A study of Actinobacillus pleuropneumoniae with 14 samples.

How the data were processed

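Genomic DNA of 14 Actinobacillus pleuropneumoniae reference strains was measured by comparative genomic hybridisation on 2-colour Agilent oligonucleotide arrays with probes of 60 bases. Per the labels, DNA was extracted with a column kit from overnight cultures, labelled with random primers, the strain with Cy5 and JL03 with Cy3, and each strain was hybridised on 1 array. No dye swap and no replicate array was among the samples, so a strain's DNA, its labelling and its array cannot be separated, and no test between strains was possible.

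Per the file headers, the scanner files follow the layout of Agilent Feature Extraction and hold the deposited log10 ratio of the red over the green channel for 42678 features, of which 1417 are control spots. The version and settings of that software are not given in the sources used here. Channel signals, backgrounds and spot flags were not used here, so the depth of the hybridisation is unknown for each spot. The authors' deposited value table holds a score for 32690 probes. Set against the scanner ratios by probe name, each column was the array's ratio minus its mean, divided by its SD over all features, to within 0.00147 of a unit. A unit of log2 ratio therefore equals between 0.388 (L20) and 1.16 (S1421) of its units, and the same cutoff is a different ratio on each array. The column medians were 0.112, 0.0910, 0.268, 0.0685, 0.0776, -0.0632, 0.0697, 0.113, 0.0188, -0.0450, -0.00400, 0.0979, 0.0486 and 0.0912 in the order of serotypes 1 to 13, with 5a before 5b. Scale, centring and direction were settled by this comparison.

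Ratios were converted to log2 and centred on the median of all 41261 non-control probes of the array, without loess. The uncentred medians lay between 0.04 and 0.29. Centring on the probes of the value table was used in a first pass of the whole analysis, before it was seen that this departed from the design fixed beforehand, and is now an alternative. The planned unit was the gene, with at least 3 probes. No annotation was at hand, and windows of 10 consecutive probe numbers took the place of genes, a choice made after the data were examined. A window's value is the median over its probes, and 3270 windows were measured. A window below -1 was called reduced, below -2 strongly reduced, and above 1 higher. Runs were at least 5 neighbouring reduced windows with at most 1 other window inside, and overlapping runs of different strains were merged into regions. Pairs of arrays were compared by the number of windows called differently and by windows differing by more than 2. That bound, the bounds of -5, -3.3 and -6 for the array labelled serotype 10, the bound of 0.7 for flat probes, the class of at least 10 of 13 arrays, the choice of 1 array from each close set and the search for shared 20-base stretches were chosen after the data were examined.

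Noise was the SD of differences between neighbouring probes in windows reduced on no array, and its correlations with counts used 100000 permutations, or all pairings below 10 arrays. The 16S rRNA gene was located by standard primer sequences, the RTX repeat by the motif GGxGxD in any reading frame of a probe, and DNA uptake sequences by their 9-base core. Composition was tested by shifting the calls around the probe order in 3270 circular steps. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The calls were tested on simulated data for the comparison of divergent and higher windows per strain, with 3270 windows on each of 14 arrays and 200 of them moved. A shift of -1.5 was recovered in at least 80% of the moved windows (median 100%), -3 and -6 in 100%, and 1.5 in at least 90% (median 97%). At most 13 unmoved windows were called reduced and 1 higher. Simulated values were drawn 1 by 1 from the array's own probes in windows reduced on no array. That choice itself keeps false calls few, so their number does not estimate those on the real arrays. The simulation leaves out regional trends along the genome.

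The rule for named items was fixed before the data were examined and was applied to windows. It took the 10 windows reduced on most arrays, the 10 lowest of those reduced on all 13 other-serotype arrays and not on S1421, the 2 lowest of each strain, the 5 longest runs, the 10 highest windows, the 10 lowest of S1421, and up to 5 windows per direction between 5a and 5b. Members of toxin, capsule and O-antigen gene lists, and of the other gene lists, could not be named, and the smaller regions and the array labelled serotype 10 were described after their values were seen. The alternatives covered the cutoff, an array-specific cutoff, the value table, the centring, the mean over probes, the share of probes below the cutoff, the minimum of probes, odd and even probes, the run length and the higher-ratio cutoff. The window size, exact zeros, GC correction, 2 further centrings and 2 sets of arrays were added after the data were examined. Background correction by normexp, loess, the filter on dim or flagged probes, bounds for spots near background, centring on ribosomal protein genes, and slide as a batch were not run, because they need channel signals, flags, slide names or an annotation that were not used here.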

Results

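Actinobacillus pleuropneumoniae is the Gram-negative bacterium that causes pleuropneumonia of pigs, and its serotypes are told apart by surface polysaccharides. Genomic DNA of the reference strains of 14 serotypes and subtypes was labelled with Cy5 and hybridised against Cy3-labelled DNA of strain JL03, which belongs to serotype 3. The strains were 4074 (serotype 1), 4226 (serotype 2), S1421 (serotype 3), M62 (serotype 4), K17 (serotype 5a), L20 (serotype 5b), Femφ (serotype 6), WF83 (serotype 7), 405 (serotype 8), CVJ13261 (serotype 9), D13039 (serotype 10), 56153 (serotype 11), 1096 (serotype 12) and N-273 (serotype 13). Each strain had 1 array, so no value has a replicate. Every ± is an SD over the probes of a region, or over arrays where that is said, and the number of arrays limits the precision. Each array carried 41261 probes of 60 bases, of which 32690 stood in the deposited value table. These 32690 probes represent JL03 and are numbered in an order in which neighbouring probes gave similar ratios. Neighbouring probes correlated with r between 0.76 and 0.87 on the 13 arrays of other serotypes and 0.37 on the S1421 array, across probes, and by at most 0.0088 in size after the order was shuffled. The probes carry no gene names in the data used here, so regions are given by probe number. A window of 10 consecutive probe numbers is called reduced where its median log2 ratio of strain over JL03 lay below -1, which does not separate an absent sequence from a diverged one.

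The first comparison asked which parts of the JL03 genome were divergent in each reference strain. Of 3270 windows, 2350 (71.9%) were not reduced on any of the 14 arrays and 920 were reduced on at least 1. The S1421 array, of the same serotype as JL03, had 27 reduced windows (0.826%). The 13 strains of other serotypes had between 211 and 429 reduced windows, with a median of 322 (9.85%). Strain CVJ13261 of serotype 9 had the most with 429, followed by 4226 of serotype 2 with 362 and 4074 of serotype 1 with 358, and M62 of serotype 4 had the fewest with 211. The counts for serotypes 5a, 5b, 6 and 7 were 351, 322, 314 and 325. Those for serotypes 8, 10, 11, 12 and 13 were 280, 340, 302, 313 and 319. A ratio below -2 was reached in a median of 164 windows on the 13 arrays (98 to 196) and in 15 windows on the S1421 array. A cutoff of -1.5 moved the median count to 209. The order of the strains depended on the setting, as centring on the mode of the ratios (median 514) put D13039 highest with 653 and 1096 lowest with 279, and the value table put 4074 highest with 208 and Femφ lowest with 127. The S1421 array had fewer reduced windows than each of the other-serotype arrays under each alternative that recounted them.

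**Figure D1:**
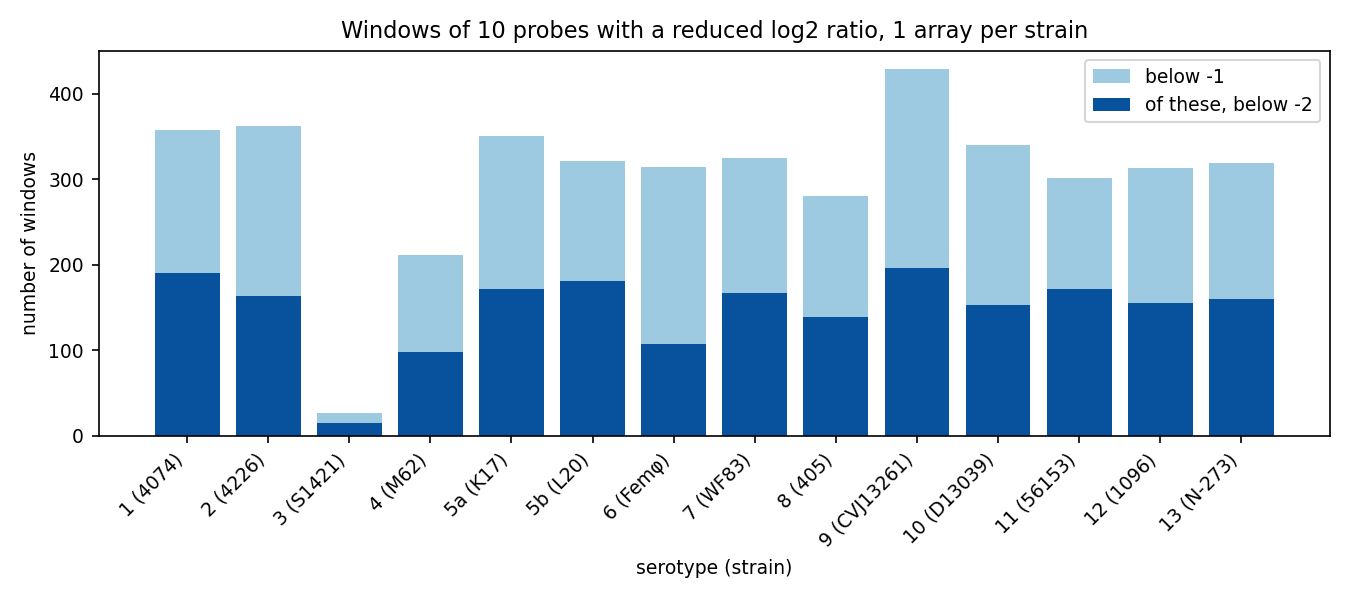
Bars give the number of windows of 10 probes (y axis, of 3270) with a median log2 ratio below -1 (light) and below -2 (dark) for each serotype and strain (x axis, 1 array each). The S1421 array has 27 windows below -1 and the others between 211 and 429.

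The noise of an array, taken as the SD of the difference between neighbouring probes in windows reduced on no array, lay between 0.65 and 0.96 on the 13 arrays and at 0.92 on the S1421 array. Over all 14 arrays the number of reduced windows had a Pearson correlation of -0.111 with noise (permutation p = 0.712, two-sided, adjusted p = 0.712) and a Spearman correlation of 0.345 (permutation p = 0.227, adjusted p = 0.284). Without L20 and S1421, the 2 arrays farthest from the median noise, Pearson's r was 0.776 (permutation p = 0.0027, adjusted p = 0.0137) and Spearman's rho 0.741 (permutation p = 0.0082, adjusted p = 0.0410). The lack of a relation over all 14 arrays therefore rested on those arrays. Without S1421 alone, rho was 0.643 over 13 arrays (permutation p = 0.0205, adjusted p = 0.0512). Within the 8 arrays whose files have 19 columns rho was 0 (exact permutation p = 1), and within the 6 with 20 columns it was 0.657 (exact permutation p = 0.175). The adjusted values cover 5 relations per coefficient.

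Reduced windows were shared between strains and clustered along the genome. Of the 3270 windows, 252 were reduced on exactly 1 of the 13 arrays of other serotypes, 148 on at least 10 of them and 29 on all 13. Of those 29, 26 were not reduced on the S1421 array, and 3 were. Independent draws with each array's own share would give 2.598e-10 windows on all 13, but several arrays were close to each other and are not independent. With 1 array kept of serotypes 1, 7 and 11, 1 of 5a, 8, 10 and 13, and 1 of 5b and 9, 34 windows were reduced on all 7 arrays, where independent draws would give 2.484e-04. Among windows reduced on a single array of the 13, strain 4226 of serotype 2 had 62, CVJ13261 had 40, Femφ of serotype 6 had 34 and 405 of serotype 8 had none. The arrays of serotypes 5a, 7, 8, 11 and 13, each almost alike to another array, had 12, 4, 0, 1 and 3, and an almost alike partner lowers such a count by construction. Runs of at least 5 neighbouring reduced windows numbered 13 per strain in the median (6 to 20), and the S1421 array had 1. Merged over strains, the runs gave 32 regions with 336 windows, or 10.3% of all. Of these regions, 9 lay below -1 in their median on at least 10 arrays, 6 on a single array, and 16 had a lowest array median under -5. With at least 80% of the probes of a window required below the cutoff, 10 windows remained below on all 13 arrays.

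**Figure D2:**
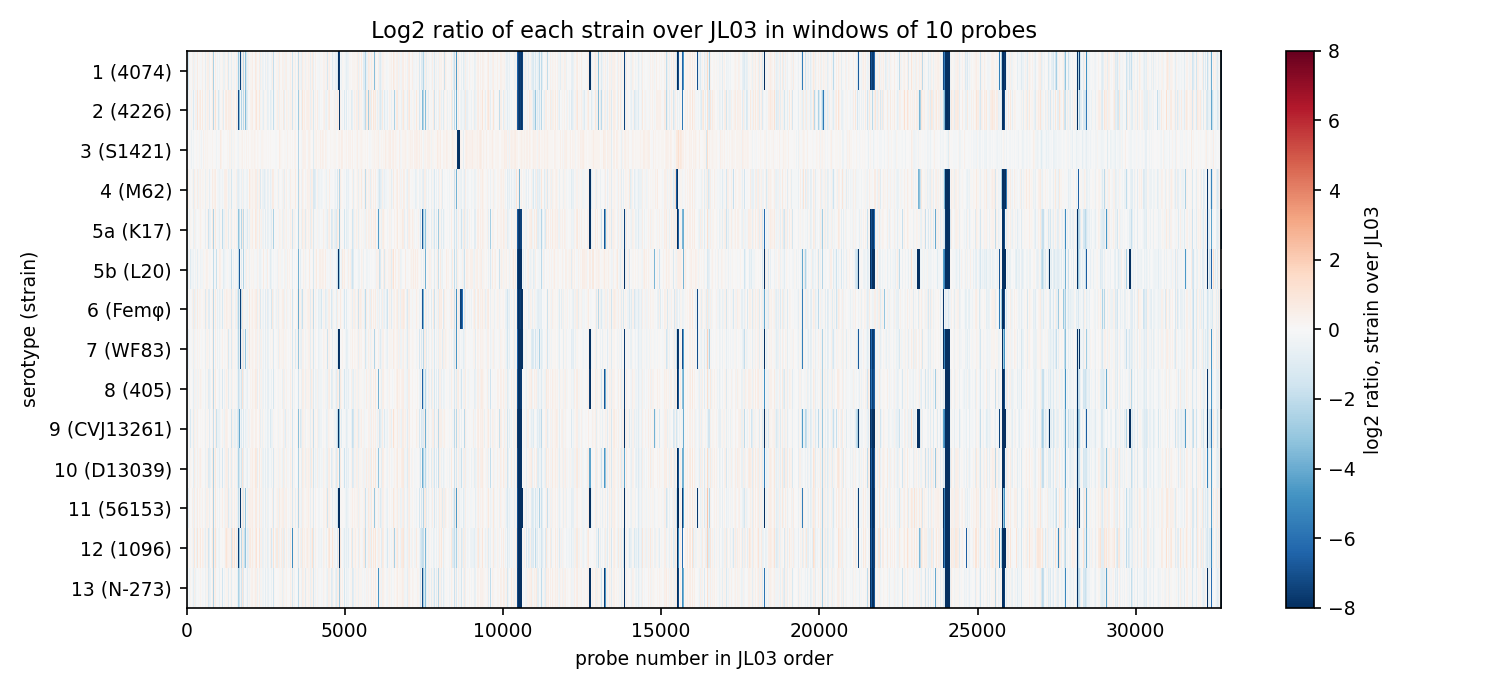
Each line is 1 array (y axis, serotype and strain) and each column a window of 10 probes in the order of the probe numbers (x axis). Colour gives the log2 ratio of strain over JL03 from -8 (blue) to 8 (red), and long blue stretches such as probes 23901 to 24140 recur on 12 of the 14 arrays.

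The longest run lay at probes 23901 to 24140 and spanned 23 reduced windows on the array of strain 4226. Its 240 probes had a median of -7.49 ± 2.79 there, and the region lay below -1 on 12 arrays, with S1421 (-0.06 ± 0.82) and Femφ (-0.52 ± 2.19) as the exceptions. Its GC content was 33.6%, against a mean of 42.0% over all windows. The next run, probes 10421 to 10620, had 20 reduced windows and a median of -8.15 ± 2.62 on the array of strain 56153. It lay near 0 on the arrays of S1421 (0.26 ± 0.63) and M62 (-0.22 ± 2.03) and below -7 on the other 12. The run at probes 25731 to 25920 had 19 reduced windows on the array of M62, with a median of -7.77 ± 2.88 and a GC content of 35.7%, and was the only one of the 5 longest to lie below -1 on all 13 arrays. The run at probes 21571 to 21730, with 16 reduced windows, had a median of -8.14 ± 1.56 on the array of CVJ13261. It divided the strains into 10 with a median below -7 and 4 (serotypes 2, 3, 4 and 6) with medians between -0.09 and 0.06. The fifth place was shared by probes 23051 to 23180, 13 windows, and probes 7421 to 7560, 13 windows. The former lay at -8.51 ± 2.31 on the array of CVJ13261 and -8.67 ± 2.50 on that of L20, at -1.51 ± 2.20 on that of M62, and above -1 on all others. The latter was milder, with -2.37 ± 2.69 on the array of K17.

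The most uniformly reduced sequence outside serotype 3 lay inside the region at probes 25711 to 25920. Its 3 windows from probe 25751 to probe 25780 averaged -8.14 ± 0.28, -8.30 ± 0.34 and -8.74 ± 0.37 over the 13 arrays (SD over arrays), with -0.18, 0.05 and -0.03 on the S1421 array. The lowest probe, App_025772 (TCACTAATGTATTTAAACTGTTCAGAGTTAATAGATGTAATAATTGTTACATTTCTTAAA), averaged -9.35 ± 0.78 over the 13 arrays. The windows at probes 23971 to 23980 and 10501 to 10510, in the 2 longest runs, averaged -8.20 ± 0.81 and -7.65 ± 1.20 over the same arrays. Signal over background is not known, so differences among ratios this low may follow the floor of each array. Beyond probe 25780 the region differed between strains. The window at probes 25841 to 25850 lay at -9.44 on the array of L20 and at 0.52 on that of strain 405. A further 3 windows reduced on all 13 arrays, at probes 3511 to 3540, were reduced on the S1421 array as well, at -2.28, -2.34 and -2.67. Over the 13 arrays they averaged -2.3 ± 0.8, -2.6 ± 0.8 and -2.7 ± 0.8 (SD over arrays). These levels lay well above those at probes 25751 to 25780. JL03 DNA was the reference on every array, so a drop shared by all arrays may come from the reference or from the strains. The cause was not tested, and these windows are not read as absent or diverged in the strains.

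Outside S1421, the 2 lowest windows of each array lay in the 3 longest runs or at probes 15481 to 15490, and the lowest ratio of all was -9.62, on the array of L20. That rank may follow the level of the array. The run at probes 23901 to 24120, for example, lay at -8.87 on the array of L20 and at -7.82 on that of 4074. Smaller regions set other groups of strains apart. Probes 29761 to 29860 lay at -7.43 ± 3.48 on the array of L20 and -7.54 ± 3.62 on that of CVJ13261 and above -1 on the 12 others. These are medians, and 60%, 50% and 50% of the windows there were reduced on the arrays of serotypes 1, 7 and 11. Probes 18221 to 18270 had medians between -7.11 and -5.81 on the arrays of serotypes 1, 5b, 7, 9 and 11 and above -1 on the others. The split was partial, as 40% of the windows there were reduced on the arrays of serotypes 5a, 6, 8, 10 and 13. Probes 15451 to 15540 lay below -4 on 9 arrays and at 1.08 ± 0.84 on the S1421 array. Probes 27361 to 27500, by contrast, had a GC content of 44.1% and lay only slightly below the cutoff, at -1.24 ± 1.24, on the array of strain 4074 alone. In all, 14 of the 32 regions had no array median at or below -2.5.

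**Figure D3:**
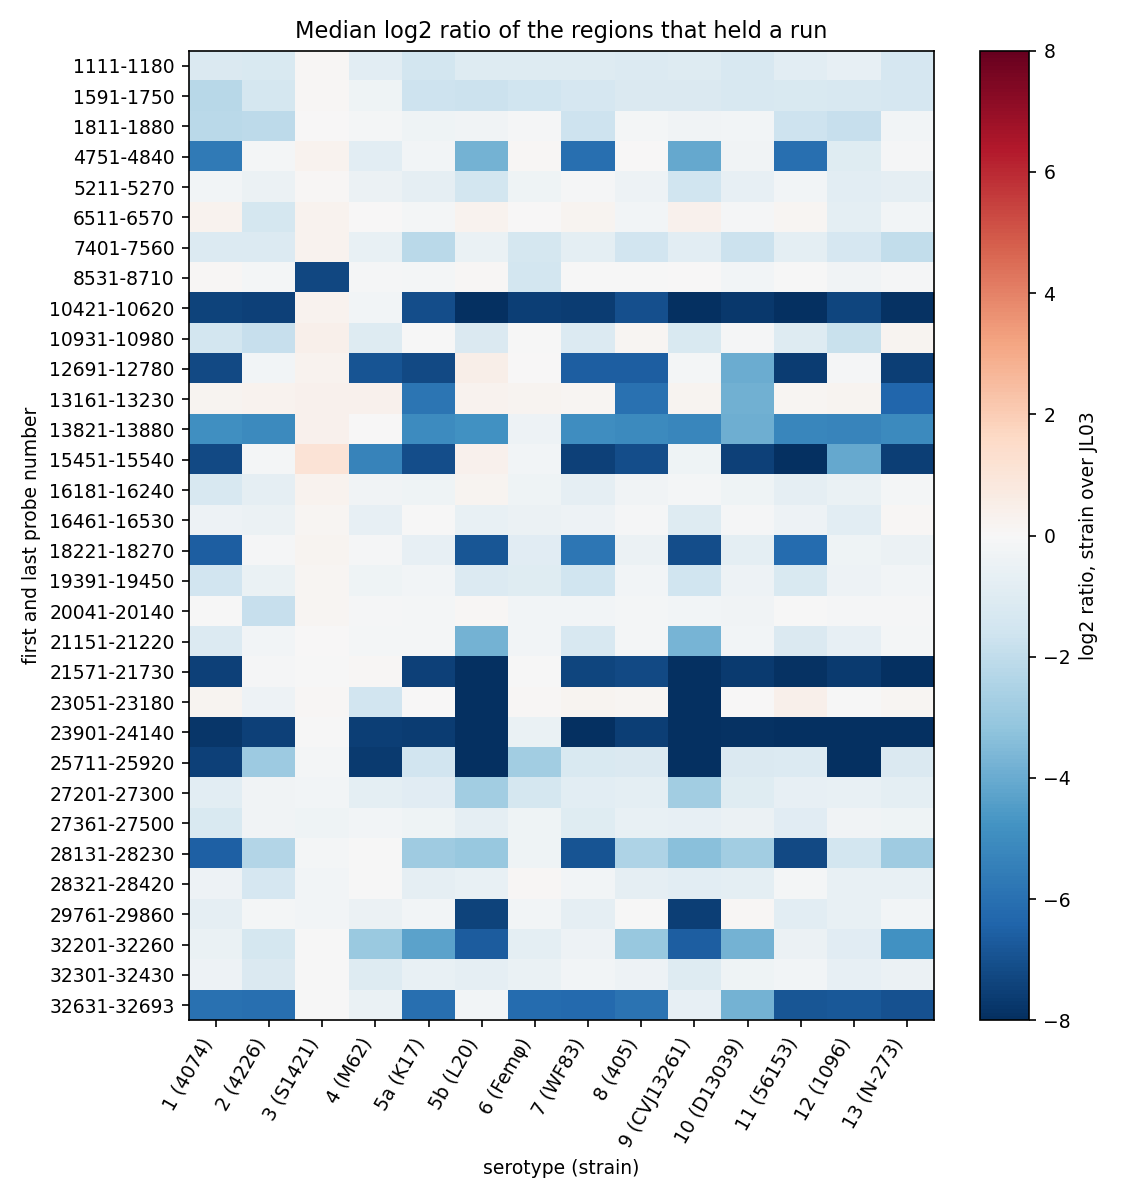
Each line is 1 of the 32 merged regions (y axis, first and last probe number) and each column 1 array (x axis, serotype and strain). Colour gives the median log2 ratio over the probes of the region from -8 (blue) to 8 (red), and the region at probes 8531 to 8710 is blue on the S1421 array and paler on the Femφ array.

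Within serotype 3, S1421 differed from JL03 in only 1 run of at least 5 windows. Probes 8531 to 8640, 11 windows and 110 probes, had a median of -8.0 ± 1.35 on the S1421 array, while the medians of the 13 other arrays lay between -0.08 and 0.18. The lowest probe there, App_008615 (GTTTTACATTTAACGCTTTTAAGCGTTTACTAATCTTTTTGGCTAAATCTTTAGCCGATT), lay at -8.96 on the S1421 array and averaged 0.08 ± 0.25 over the 13 others. The array of Femφ, serotype 6, had a run of 8 reduced windows at probes 8631 to 8710, at -7.19, which overlapped the end of the S1421 run at probes 8631 to 8640. The 10 lowest windows of the S1421 array all lay in its run and ranged from -8.35 to -7.30. Of its 27 reduced windows, 11 lay in that run, and the others, such as those at probes 3511 to 3540, lay outside it. With runs of at least 3 windows it had 3.

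Ratios above 1 were rare and small beside the reductions. They were found in 100 windows on the array of strain 1096 (serotype 12), in 45 on that of 4226 (serotype 2) and in a median of 5.5 on the other 12 arrays. Both arrays shared 26 of them, where independent lists would share 1.38. All arrays share the probes and the JL03 reference, however, and these 2 correlated at 0.73 over windows reduced on no array. The lists are therefore not independent, and the overlap alone shows no shared gain. The highest window over all arrays was App_016441 at 2.21 ± 0.27 on the array of strain 56153, and the same window lay at 1.86 ± 0.36 on that of 1096 and at 1.83 ± 0.09 on that of WF83. The adjoining window App_016431 lay at 1.81 ± 0.91 on the array of D13039 and at 1.73 ± 0.97 on that of 56153. The arrays of 1096 and 4226 also had the widest window spread of the 14, with an SD of 0.47 and 0.46 over windows reduced on no array, so that a fixed cutoff is passed more easily there. The count for 1096 rests on the centring as well, with 100 higher against 313 reduced windows as given, 172 against 279 on the mode and 270 against 250 on the 16S rRNA probes. For 4226 the split was 45 against 362 as given, 180 against 288 on the mode and 169 against 295 on the 16S rRNA probes.

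Sequence features known beforehand were used to look for 2 kinds of locus without an annotation. Standard primer sequences of the 16S rRNA gene matched probes at 4 places, and the array medians of those places lay between -0.98 and 0.05. A glycine-rich nonapeptide repeat names the RTX toxins, the family of the Apx cytolysins of this species. Its motif GGxGxD, read in any frame of a probe, was found in 19 probes of the value table. In 4 clusters there were at least 2 such probes. How many probes would carry the motif by chance was not computed. The cluster at probes 21658 to 21661 lay inside the run at probes 21571 to 21730, with medians between -8.51 and -6.70 on 10 arrays and between -0.57 and 0.11 on those of serotypes 2, 3, 4 and 6. The cluster at probes 16439 to 16483 had medians between -0.23 (L20) and 1.77 (1096), and that at probes 15546 to 15552 between -0.02 (Femφ) and 1.05 (1096). The cluster at probes 28517 to 28536 lay between -0.88 and 0.25. The motif alone does not tell which toxin gene, or whether a toxin gene, a cluster belongs to.

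Serotypes 5a and 5b are subtypes of a single serotype, and their reference strains K17 and L20 were set beside all 91 pairs of arrays. They differed in the call of 325 windows, which was the 52nd smallest of the 91 distances, and in 124 windows by more than 2 on the log2 scale. Probes 23061 to 23170 lay at -8.75 ± 0.53 on the array of L20 and at 0.19 ± 1.76 on that of K17, and probes 4751 to 4800 at -6.71 ± 3.50 against 0.27 ± 1.42. Probes 27231 to 27270 lay at -8.44 ± 2.09 on the array of L20 and at -0.45 ± 2.31 on that of K17. In the other direction, probes 12711 to 12760 lay at -8.11 ± 2.19 on the array of K17 and at 0.71 ± 0.71 on that of L20, and probes 15471 to 15530 at -7.80 ± 1.02 against 0.62 ± 0.62. Probes 32661 to 32693, the end of the numbered order, lay at -6.82 ± 0.71 against -0.14 ± 0.65. The distance was 129 to 844 windows under the alternatives, and a distance between single arrays has no test. The K17 array was itself almost alike to those of serotypes 8 and 13, with 54 windows called differently from serotype 13. That of L20 differed from that of CVJ13261 by more than 2 in only 6 windows. Over windows reduced on no array, L20 correlated at -0.03 with K17, against a median of 0.65 over pairs without S1421. Its correlation with each other array except S1421 was 0.23 or less. With S1421 it was 0.60, while S1421 correlated at 0.30 or less with every array but L20. These were also the 2 arrays with the highest noise (0.96 and 0.92). The low correlation of L20 with K17 is thus not particular to that pair, and its cause was not tested. Exchanged labels are not excluded, so the distance need not be that of the subtypes.

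Several arrays of different serotypes were almost alike. In 4 of the 91 pairs, 7 with 11, 5a with 13, 8 with 13 and 5a with 8, no window differed by more than 2, and the largest difference was 1.90. The correlation over windows was 0.995, 0.991, 0.993 and 0.985 in these pairs, whereas it was 0.688 in the median over pairs without S1421 and between -0.01 and 0.07 for pairs with S1421. The other pairs differed by more than 2 in a median of 124 windows (6 to 209). The array of 4074 (serotype 1) stood close to those of WF83 and 56153 and differed from both at probes 25781 to 25870, where it lay at -7.95 ± 1.79 against -2.59 ± 2.35 and -2.52 ± 2.43, and at probes 25641 to 25680, where it lay at -2.15 ± 2.77 against -0.57 ± 2.04 and -0.47 ± 2.14. At probes 1681 to 1720 it lay at -7.14 ± 1.93 against -2.54 ± 2.95 on the array of WF83. L20 and CVJ13261 differed by more than 2 in 6 windows, of which probes 1641 to 1690 (-6.56 ± 2.42 against -1.58 ± 2.13) held a run. The number of pairs with no window differing by more than 2 was 1 on odd-numbered probes alone and 1 on even-numbered probes alone.

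**Figure D4:**
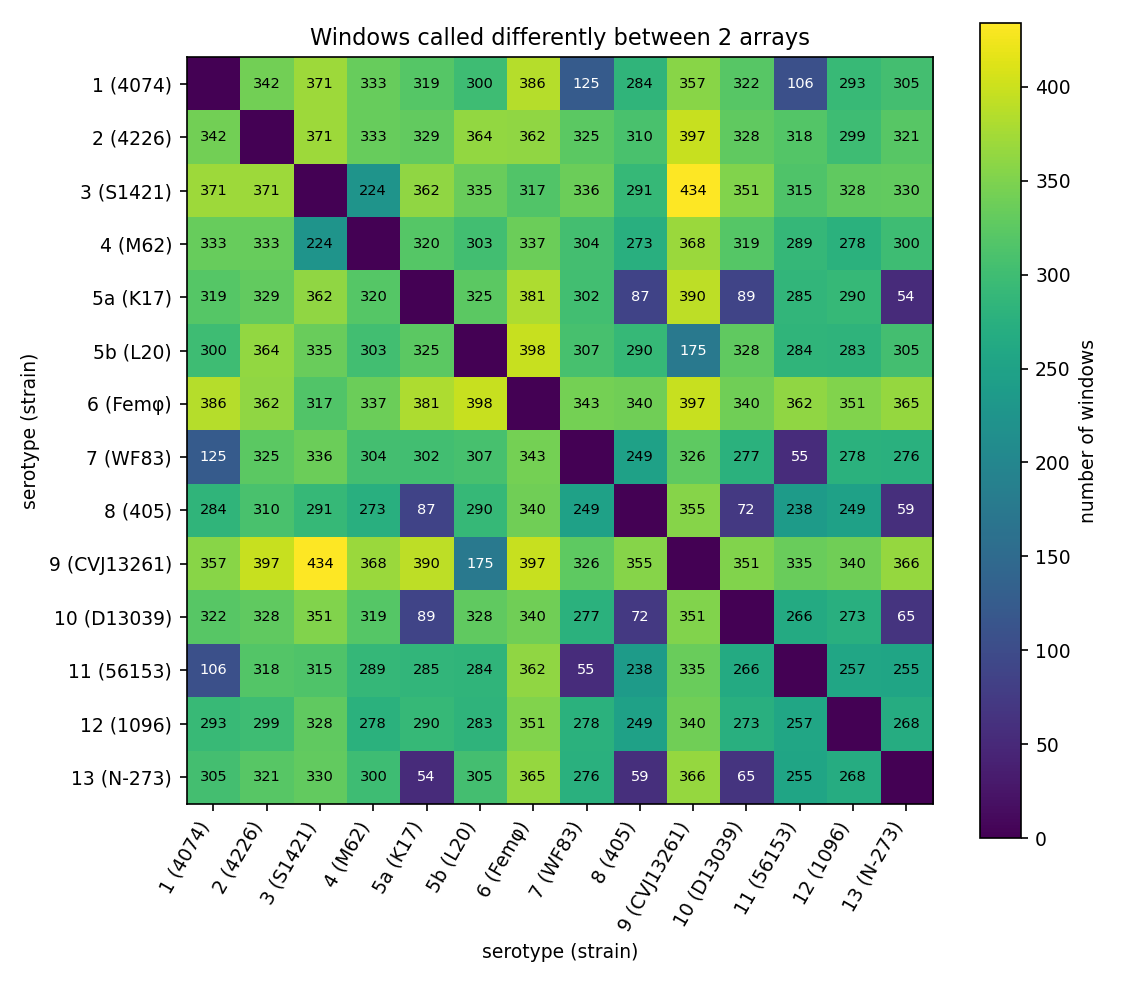
Each cell gives the number of windows (of 3270) called differently between the array of its line and that of its column, for 14 serotypes and strains. The smallest value is 54 for serotypes 5a and 13, and 5a and 5b differ in 325.

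The array labelled serotype 10, strain D13039, followed those of 5a, 8 and 13 over most of the genome and differed at 5 places. Of 867 probes below -6 on the arrays of 5a, 8 and 13, 155 (17.9%) lay between -5 and -3.3 on the array labelled serotype 10, with a median of -4.23 ± 0.36. Each of the 3 other arrays set beside the remaining pair had at most 0.867% of its probes in that range. Regions of at least 20 probes built around such probes, which hold some probes outside that range, lay at probes 12708 to 12755, 13164 to 13196, 13822 to 13848, 32226 to 32251 and 32657 to 32693, with medians of -4.16 ± 0.29, -4.24 ± 0.40, -4.33 ± 0.39, -4.89 ± 0.64 and -4.54 ± 0.98. At the first of these, the arrays of 5a, 8 and 13 lay at -8.15 ± 0.49, -7.73 ± 0.74 and -8.69 ± 0.65, and that of L20 at 0.72. L20 and CVJ13261 lay at -8.74 and -8.67 in the third region and at -8.62 and -8.67 in the fourth, and the S1421 array alone was near 0 in all 5. The bounds of the range were chosen after the values were seen.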

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

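All tests weighed here except that of array noise against the counts of all arrays were chosen only after the result was seen.

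Probes outside the deposited value table entered the centring and the checks of alike arrays and of the array labelled serotype 10, but none of the counts of windows. They number 8571, of which 4019 share no stretch of 20 bases with the JL03 probes, and they fall into 3 sets by probe number. In the first set, 84.4% of the 2954 probes without a shared stretch lay above a log2 ratio of 2 on the array of L20. The share was 66.5% on the array of CVJ13261 and 38.0% on that of D13039. It was 1.18% on the S1421 array and 22.99% in the median of the 13 other-serotype arrays. In the second, 68.5% of 1023 lay above 2 on the array of CVJ13261, against 0.782% on that of S1421 and 11.9% in the median. In the third, 52.4% of 42 lay above 2 on the array of 4074, against 2.38% on that of S1421 and 19.05% in the median. The arrays of WF83 and 56153 followed with 42.9% and 40.5%. High shares were thus not confined to 1 array in any set. The third set holds only 30 distinct sequences, and 11 of the 13 arrays lay above S1421 in it, L20 and CVJ13261 being at 0%. The sequences these probes stand for were not named here. Between 5a and 5b, 1 window went opposite ways beyond the cutoffs. It was App_016441, at 1.20 on the array of K17 and -1.20 on that of L20, and with 1 array each the difference was not tested.

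The numbers of reduced windows differed between strains, and array noise had a Spearman correlation of 0.345 with them over all 14 arrays (permutation p = 0.227), and 0.741 without L20 and S1421 (permutation p = 0.0082, adjusted p = 0.0410). Counts on odd-numbered and even-numbered probes of 1 array differed by at most 38 (Femφ), which met the bound of 40.2 written beforehand. That bound was scaled to the range over all 14 arrays (402). The range rests on S1421 with 27, against 211 to 429 on the others. The margin to the bound was smaller than the SD of these differences (10.8), a condition that was not written beforehand. The bound thus does not settle the differences among the other-serotype arrays. Noise may therefore account for part of the differences among the other-serotype arrays, and the data do not decide it. For S1421, probe noise was high (0.92) but the spread of its windows was the lowest of the 14 arrays (0.25, others 0.32 to 0.47), and the tables argue against noise as the whole cause of its low count, because each of the 13 others had at least 71 reduced windows that recurred on at least 10 of the remaining 12, against 27 reduced windows in all on S1421. Within windows reduced on no array, the slope of the ratio on GC predicted a shift of 0.0281 in the median of the 13 (-0.0050 to 0.1186). A slope of that size would not give the observed -4.65. That value comes from windows chosen for being low, however, and the slope from windows not below -1 on any array. Neither addresses why counts differ between strains. A GC effect on the counts is thus not decided. Yet 16 of the 32 regions had a lowest array median under -5, while their highest array medians lay between -0.13 and 1.08. Steps of that size between arrays at the same probes exceed the noise of 0.65 to 0.96. They argue against noise or that slope as the whole cause in those regions. How far gene content sets the counts remains a hypothesis.

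In 4 of the 91 pairs of arrays, with different serotype labels, no window differed by more than 2. Probe behaviour or the JL03 reference, common to all arrays, would make most pairs alike, and the tables argue against it with those 4. Joint processing remains open, because no label names a batch and the layout of a file need not mark one. Of the 4 alike pairs, 3 joined files of different layouts. Pairs of 1 layout had a mean distance of 293 against 286 in pairs of 2 (a gain in closeness of -2.47%, pairs with S1421 left out). Within the alike pairs at most 2.67% of the probes outside the value table differed by more than 2, against a median of 19.96% in the other pairs, and the largest window difference was 1.90. The same DNA on more than 1 array, exchanged labels and close kinship of the strains could each give these values and cannot be told apart, because no array was repeated.

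On the array labelled serotype 10, regions below -6 on 5a, 8 and 13 lay near -4. JL03 DNA in the Cy5 channel would lift all such probes, and 79.2% of them lay below -6 there, which argues against it. Diverged copies remain open, because the probe SD ranged from 0.29 to 0.98 over the 5 regions and the choice of the regions by their level itself kept it small. A second genome in the labelled DNA may be a candidate explanation and remains open too. Probes outside the value table that were flat on 5a, 8 and 13 lay above 2 on this array in 6.16% of cases. That was 8.18 times the highest share of 5a, 8 and 13 (0.753%), each set likewise beside the 3 others of these 4 arrays. But sequence of the strain's own would do the same, and the share was higher on 6 other arrays. It was 30.1% on L20, 28.2% on CVJ13261, 8.57% on 4074, 7.51% on 56153, 7.22% on WF83 and 6.33% on 1096. The flat probes above 2 on the array labelled serotype 10 had medians of 8.45 on L20 and 6.61 on CVJ13261. Yet L20 and CVJ13261 lay below -8 at probes 13822 to 13848 and 32226 to 32251, and the S1421 array alone was near 0 in all 5. S1421 was also near 0 at probes 21571 to 21730 and 23901 to 24140 (-0.03 and -0.06). The array labelled serotype 10 lay at -7.65 and -7.88 there. These values argue against a single other strain of the 14 as the second genome. They leave open a genome from elsewhere or more than 1.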

How the results depend on the processing

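The window sizes, exact zeros, GC correction, centring on value-table or 16S rRNA probes and the sets of arrays left out were chosen only after the result was seen.

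Over 23 settings, 15 of them planned, 566 values were recomputed, of which 347 stayed within 1.5 times or kept their call, 206 moved beyond that and 13 changed sign. Of 261 counts for single strains, 102 moved. No value moved when exact zeros were left out, after GC correction, or without the arrays labelled serotypes 8 and 10, and the minimum of 1 or 5 probes left nearly every window as it was and tests nothing. Against the median of all probes, the other centrings shifted array zero points by -0.20 to 0.41 (mode), -0.74 to -0.06 (16S rRNA) and -0.14 to 0.07 (value-table probes), and the reductions are reported relative to the first. Where no cause is named, the cause was not tested. Signal over background is not known for these arrays, which limits every count near the cutoff and the exact level and rank of the lowest ratios. The filters on dim or flagged probes, normexp, loess, ribosomal protein centring, gene lists and slide as a batch were not run. With 1 array per strain, no replicate could be left out.

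Stricter calls gave fewer windows by construction. The median, lowest and highest counts of the other serotypes were 209, 124 and 261 at a cutoff of -1.5, 164, 98 and 196 at -2, 208, 136 and 256 at 3 robust SDs below the array median, and 150, 86 and 192 where 80% of the probes had to lie below. S1421 then had 15, 15, 47 and 15 reduced windows, so that the array-specific cutoff raised its count. The highest count was that of 4074 at 3 robust SDs and on the 16S rRNA probes (256 and 329), where CVJ13261 had 235 and 226. In the same order, 560, 389, 544 and 410 windows were reduced in at least 1 strain, 13, 11, 12 and 10 in all strains of other serotypes, and 13, 11, 12 and 8 in all of these and not in S1421. Serotypes 5a and 5b differed in 197, 131, 198 and 131 windows. Runs numbered 7 in the median at 80% of the probes.

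The authors' value table, whose unit differs between arrays, gave a median, lowest and highest count of 162, 127 and 208, with 43 for S1421. It gave 446 windows in at least 1 strain, 11 in all of the other serotypes and 11 without S1421, 129 between 5a and 5b, and 8 runs in the median. Higher windows numbered 1 for serotype 12, 0 for serotype 2 and 0 in the median of the other arrays.

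Centring on the mode raised the median and highest counts to 514 and 653. Higher windows then numbered 172 for serotype 12, 180 for serotype 2 and 2 in the median of the others. Centring on the 16S rRNA probes lowered the lowest count to 128, the windows reduced in all other serotypes to 15 and those not in S1421 to 13, and gave 270, 169 and 49 higher windows. On the value-table probes serotype 2 had 73 higher windows.

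A cutoff of 0.75 gave 298, 230 and 33.5 higher windows for serotype 12, serotype 2 and the median of the others, a cutoff of 1.5 gave 2, 0 and 1, and the mean over probes gave 47 and 26 for serotypes 12 and 2. Runs of at least 3 windows numbered 30 in the median and 3 for S1421, and runs of at least 10 numbered 3 in the median.

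Odd-numbered probes gave 65 reduced windows for S1421, 90 higher windows for serotype 2, 9 in the median of the others and 1 alike pair, and even-numbered probes gave 54, 85, 9.5 and 1. These medians rest on fewer probes.

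Windows of 5 probes, more numerous by construction, gave a median, lowest and highest count of 823, 578 and 1112, with 139 for S1421. They gave 2318 windows in at least 1 strain, 4221 in none, 68 in all of the other serotypes and 56 without S1421, 844 between 5a and 5b, 27 runs in the median, 3 for S1421 and 1 alike pair. Higher windows numbered 427, 324 and 45.5. Windows of 20 probes gave 128, 67 and 163, with 10 for S1421, 348 in at least 1 strain, 1287 in none, 9 in all of the other serotypes, 8 without S1421, 129 between 5a and 5b and 6 runs. Higher windows numbered 10, 2 and 1.

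The Spearman correlation of counts with noise turned to -0.125 with the value table, -0.0286 on the mode and -0.0725 on the 16S rRNA probes, and was past its threshold under none of the alternatives to the processing, although it was past it without L20 and S1421 (0.741, permutation p = 0.0082). The distance within cross-reacting sets minus that outside changed sign to 0.857 at a cutoff of -2, 2.52 at 3 robust SDs, 0.798 at 80% of the probes, 4.58 with the value table, 29.4 on the mode and 3.36 with the mean. It was 10 and 2.39 on odd and even probes, 13.7 with windows of 5 probes and 4.12 with 1 array of each alike set, and the cause was not tested.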

Other observations

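The tests of composition were chosen only after the result was seen, and the test of cross-reacting serotypes was written before.

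Regions reduced in most strains differed in composition from the rest of JL03. The 148 windows reduced on at least 10 of the 13 other-serotype arrays had a GC content of 37.9% ± 5.41 (SD over windows), the 309 reduced on 4 to 9 had 41.3% ± 4.64, the 452 reduced on 1 to 3 had 42.8% ± 3.17 and the 2361 reduced on none had 42.3% ± 3.43. The 9 regions below -1 on at least 10 arrays had a median GC content of 36.9%. Shifting the calls around the probe order never gave as large a difference in GC as the -4.34 percentage points observed (permutation p = 3.058e-04, the smallest the shifts can give, adjusted p = 9.174e-04). Chance placement along the genome is thus argued against, and acquisition of these regions from elsewhere may be considered only as a hypothesis that was not tested.

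The 9-base core of the DNA uptake sequence, which marks DNA for uptake in this family of bacteria, was found in 14 of 1473 probes of the windows reduced on at least 10 arrays, or 9.50 per 1000, and in 12.9 per 1000 of the windows reduced on none. This difference of -3.37 per 1000 may be chance placement (permutation p = 0.263, adjusted p = 0.263 over 3 relations). Windows reduced on 1 to 9 arrays carried 3.15 per 1000 more than those reduced on none (permutation p = 0.0315, adjusted p = 0.0472).

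Serotypes whose antisera are known to cross-react, 1 with 9 and 11, 3 with 6 and 8, and 4 with 7, were compared by the number of windows called differently. The mean distance was 293 in the 7 pairs within these sets and 296 in the 84 other pairs, a difference of -2.92 (one-sided permutation p = 0.438). The sign changed under 10 of the alternatives. Serotypes 1 and 11 differed in 106 windows, and the other pairs within the sets in 291 to 357. The lower mean within the sets thus rested on serotypes 1 and 11. The pairs of serotype 3 with 6 and with 8 include S1421. Shared ancestry of cross-reacting serotypes may or may not leave a trace in these arrays, and the data do not decide it.

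The probes with the RTX motif at 21658 to 21661 lay at -6.70 on the array labelled serotype 8 and near 0 on those of serotypes 2, 3, 4 and 6. The toxin ApxIII is known from serotypes 2, 3, 4, 6 and 8, and the region was not annotated here, so the array labelled serotype 8 is a case for a second look at the label or the region. That array was also a member of 2 of the almost alike pairs.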
